A study of Mus musculus with 12 samples.

How the data were processed

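RNA from mouse AECII cells, the type II alveolar epithelial cells named in the series title, was split with an antibody against N6-methyladenosine (m6A, a methyl mark on adenosines of RNA) into a bound part (IP) and an unbound supernatant (Sup). Per the labels, IP RNA was labelled with Cy5 and Sup RNA with Cy3. The 12 samples were therefore the 2 channels of 6 arrays, with 3 arrays of cells labelled as normal, with no treatment, and 3 of cells transfected with shMettl3, a short hairpin RNA against Mettl3, the enzyme that writes m6A on messenger RNA. Groups and replicate numbers came from the sample titles. No control hairpin was named in the labels. Their descriptions abbreviate the normal group as NC, which is not spelled out, so whether the comparison includes the transfection itself is not settled. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Dyes were not swapped, so dye and fraction could not be told apart for any probe.

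Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1, and the intensity values deposited as processed signals were background-subtracted, detrended and dye-normalized within each array (linear and lowess). The deposited files also give median spot and background intensities and background-subtracted intensities. Each array held 62976 spots. All 6 arrays were read in 1 scan and did not overlap in it; 1 row of the slide held the 3 shMettl3 arrays and normal replicate 1, and the other held normal replicates 2 and 3. The authors' deposited value table is on a log2 scale and holds 45155 probes. Set against the scanner values, each of its columns was the log2 processed signal minus 1 constant, within 4.9e-09. Its direction and scale were thus known from the comparison, while the source of the constants is not given in the sources used here. The constants lay between 10.22 and 11.64 for IP and between 9.75 and 10.64 for Sup. The column medians lay between -3.19 and -1.87 for IP and between -2.27 and -1.79 for Sup. All 45155 probes met 1 rule, an IP channel well above background on at least 3 arrays, and 17 further probes that met it were not in the table.

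Control spots were left out, as were spots flagged as outliers in either channel. The spots of a probe were averaged, which left 60691 probes. Averaging mattered mainly for the 50 probes with an accession, of 10 spots each. Since 62976 spots cover all probes and controls, nearly all other probes have 1 spot, and their values are not averages. The m6A ratio was log2(IP/Sup) of the processed signals minus the median of the array over 21372 probes well above background in both channels on at least 3 of 6 arrays. The lowess dye normalization of the scanner software was already in these signals, so a shift of many probes 1 way may be reduced in every ratio made from them. No further loess or quantile step was added. Total abundance was log2 of the sum of both channels minus the 75th percentile of the array, over 45373 probes well above background in at least 1 channel on at least 3 arrays. IP and Sup signals were scaled in the same way over 44992 and 21771 probes. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with data.table (version 1.17.8), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Intervals are 95% intervals from that fit. The array-wide ratio was compared with an exact two-sided permutation test, which cannot give a p below 0.1 with 3 arrays against 3. The threshold stated by the authors, a change of at least 2-fold with a p under 0.05, was applied with limma's unadjusted p, because their test is not given in the sources used here. The number of arrays limits the precision: the median 95% interval of a probe reached 1.54-fold either way for the ratio and 1.43-fold for abundance.

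Gene names could be given to few probes. The scanner files hold an accession for 50 probes, of 10 spots each, and 45 of these matched a symbol in the RefSeq table of assembly GRCm38.p6, used for names only because the array header names build mm9. The other probes carry array-maker IDs that the files used here do not pair with genes. Mettl3 and Pten were not among the named probes, so the knockdown was not checked and neither gene was analysed here. Of 23 gene lists fixed before the data were examined (m6A writers, erasers and readers, the Pten pathway, cell type markers and others), 2 had a named probe, with 1 member each: E2f1 of the cell cycle list and Rps4l of the ribosomal protein list. Tests of gene lists and markers of other cell types were therefore not run.

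Named genes were chosen by a rule fixed before the data were examined. For the ratio and abundance it takes up to 10 genes per direction that pass the test, are well above background on all 6 arrays and have groups that do not overlap, and, where too few pass, the lowest unadjusted p up to 5 per direction. For the level in normal cells it takes the 10 highest and 10 lowest ratios among named genes well above background in both channels on all 6 arrays. Predicted genes are passed over. A further part of the rule, probes detected in IP on all arrays of 1 group and none of the other, met no named gene.

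The fit was tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold. Noise was drawn independently for each probe and array from the probe's own estimated spread. Those estimates, each from few arrays, were taken as the true spreads, and shifts shared between probes were not simulated. Recovery in the real data may therefore differ. False calls numbered 5 for the ratio, 2 for abundance, 5 for IP and 2 for Sup. For the ratio, 6% of the 2-fold and 73% of the 4-fold changes were recovered among 20920 probes, and for abundance 8% and 71% among 44889. For IP signal the shares were 13% and 67% among 44508 probes, and for Sup signal 0% and 53% among 21319. Alternatives included another background correction (normexp with an offset of 50, on median spot signals because mean signals were not in the files), the authors' values, other filters and scalings, a replicate block, variance trends, array weights and leaving out each array. The authors' values were taken without further centring or scaling, so differences in them carry any array-wide shift. Slide row as a block and slide row 1 alone were added after the data were seen.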

Results

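The series measured how RNA of mouse type II alveolar epithelial cells, the surfactant-producing cells of the lung, divides between an m6A antibody pull-down (IP) and the supernatant (Sup). Normal cells were compared with cells transfected with shMettl3, a short hairpin against the m6A writer Mettl3. Each group had 3 arrays, and each array carried the IP and Sup channels of 1 sample. Between 40752 and 45746 probes per array were well above background in IP. Spots whose IDs begin with MM9NEGATIVE passed the same flag in IP at rates of 26.7% to 55.6%. The filters for IP and abundance use this flag, so a kept probe may carry unspecific signal. In Sup, 22182 to 23120 probes were well above background on the normal arrays, against 23723, 17961 and 16306 on shMettl3 replicates 1, 2 and 3. No spot was saturated. The named part of the array was small, with 45 probes of known gene, and Mettl3 and Pten, the genes in the series title, were not analysed here because no named probe represents them. The knockdown therefore rests on the labels.

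The first comparison asked which transcripts of normal cells lay on the IP side. Of 25 named probes measured in both channels, 16 lay above the array median and 4 below it in the limma fit. Rab5a, a small GTPase of early endosomes, had a log2 IP/Sup ratio of 3.57 ± 0.76 (SD, n = 3) relative to the array median, which is 11.8-fold. Uhrf1bp1l had one of 3.23 ± 0.73 (SD, n = 3), and Cpt1a, which controls entry of fatty acids into mitochondria, at 2.40 ± 0.28 (SD, n = 3). Bambi, a decoy receptor of TGF-beta signalling, lay at 2.18 ± 0.38, Carhsp1 at 1.45 ± 0.09, and Lhfp at 1.29 ± 0.43 (SD, n = 3). Pex11a, a protein of peroxisome division, had a ratio of 1.28 ± 0.20, and the lipid carrier Apoe one of 1.04 ± 0.40 (SD, n = 3). The glycolytic enzyme Gpi1 and the pyroptosis pore protein Gsdmd had ratios of 0.94 ± 0.44 and 0.82 ± 0.37 (SD, n = 3). On the Sup side, the antioxidant enzyme Prdx2 had a ratio of -1.58 ± 0.37 (SD, n = 3). The transcription factor Ascl1 lay at -1.11 ± 0.17 and the creatine synthesis enzyme Gamt at -0.75 ± 0.24 (SD, n = 3). Rps4l, a copy related to ribosomal protein S4 whose probe may also bind its relatives, lay at -0.59 ± 0.15 (SD, n = 3).

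The values of these genes all differed from the array median, with limma adjusted p between 3.92e-06 for Rab5a and 0.0117 for Rps4l. The fatty acid oxidation enzyme Acaa2 had a ratio of 0.62 ± 0.25 and Hspb7 one of 0.53 ± 0.45 (SD, n = 3), with limma adjusted p of 0.00879 and 0.0317. Actb, which encodes beta-actin, lay at -0.38 ± 0.09 (SD, n = 3) with a limma adjusted p of 0.0563. H2-M2, a class I histocompatibility gene with close relatives, the glutathione transferase Gsta4 and Tm9sf1 had ratios of 0.31, -0.25 and 0.06, with limma adjusted p of 0.142, 0.227 and 0.782. Over all 21372 probes the middle of the distribution ran from -0.85 at the 25th percentile to 0.86 at the 75th, and 7276 probes lay above and 7245 below the array median by the test, a balance that centring sets. Without centring 5650 lay above and 8994 below 0, with loess 6103 and 8771, and in the authors' values 4078 and 9676. Because the dyes were not swapped, a ratio of a single probe contains its dye bias, and zero is set by centring. The level was also compared under 8 alternatives. These include the level in shMettl3 cells (4.49 for Rab5a), so they are not all reprocessings of the normal arrays. The calls of Rps4l, Hspb7 and Acaa2 were lost under 4, 4 and 2 of 8 alternatives, among them for Rps4l leaving out normal replicate 2 or 3, for Hspb7 normal replicate 1 or 3 and for Acaa2 normal replicate 1 (ratios of -0.52, -0.59, 0.27, 0.64 and 0.48), and the sign of Gsta4 and Tm9sf1 turned under 1 and 3 of them. Actb, Gsta4, H2-M2 and Tm9sf1 gained a call under 3, 2, 2 and 1 of the 8, with Actb at -0.66 and Gsta4 at -0.53 without centring, H2-M2 at 0.57 among probes detected on all 6 arrays and Tm9sf1 at 0.36 with normexp. Over the 8 alternatives H2-M2 ran from 0.025 to 0.57. With normexp Ascl1 lay at -0.46 and Gamt at -0.29, and without centring Gsdmd lay at 0.54. Gamt lay at -0.49 among probes detected on all 6 arrays.

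**Figure D1:**
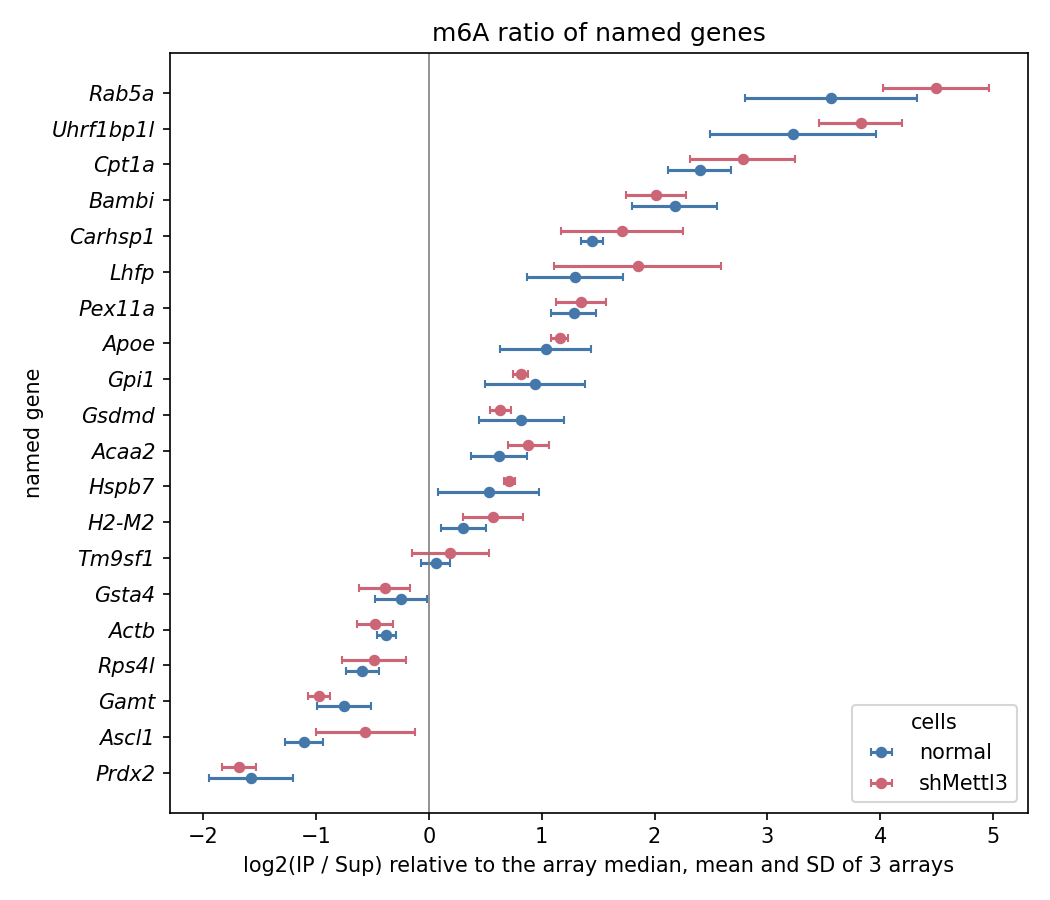
Log2 IP/Sup ratio relative to the array median (x axis) of 20 named genes (y axis), as mean and SD of 3 normal arrays (blue) and 3 shMettl3 arrays (red). Rab5a lies at 3.57 in normal and 4.49 in shMettl3 cells, and Prdx2 at -1.58 and -1.68.

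The next comparison asked whether the m6A ratio of single transcripts differed after transfection with shMettl3. No named gene passed the test, and neither did any other probe (limma, adjusted p at least 0.767). The lowest unadjusted p of a named gene belonged to Rab5a, at a log2 ratio of 4.49 ± 0.47 (SD, n = 3) in shMettl3 cells, a difference of 0.92 from normal cells (95% interval 0.04 to 1.81), with all 3 arrays above the normal mean. Ascl1 differed by 0.54 (interval -0.07 to 1.16), Uhrf1bp1l by 0.60 (-0.23 to 1.43), Lhfp by 0.56 (-0.30 to 1.42) and Cpt1a by 0.38 (-0.28 to 1.04). On the lower side, Gamt differed by -0.22 (-0.74 to 0.30), Gsdmd by -0.19 (-0.76 to 0.39), Bambi by -0.17 (-0.78 to 0.44), Gsta4 by -0.15 (-0.69 to 0.40) and Gpi1 by -0.12 (-0.73 to 0.48). The signs for Gsdmd, Bambi and Gpi1 turned without normal replicate 1, to 0.03, 0.04 and 0.12, and that of Gpi1 also with loess, to 0.21, and with array weights. Without that array Rab5a, Uhrf1bp1l, Lhfp and Cpt1a differed by 0.49, 0.20, 0.34 and 0.23, and Gamt and Gsta4 by -0.08 and -0.015. Without shMettl3 replicate 3 Uhrf1bp1l, Lhfp and Cpt1a differed by 0.39, 0.13 and 0.12, and without shMettl3 replicate 1 Ascl1 by 0.35. With slide row as a block Rab5a, Uhrf1bp1l, Lhfp and Cpt1a differed by 1.80, 1.40, 1.001 and 0.68, Gamt, Gsdmd, Bambi, Gsta4 and Gpi1 by -0.50, -0.61, -0.58, -0.41 and -0.62, and with normexp Rab5a, Ascl1 and Uhrf1bp1l by 0.61, 0.29 and 0.30. Adjusted over the 25 named probes alone, no gene passed either, with a lowest adjusted p of 0.683. E2f1, the single named member of the cell cycle list, differed by 0.41 (-0.31 to 1.14), and Rps4l, the single named member of the ribosomal list, by 0.11 (-0.44 to 0.65).

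At an unadjusted p under 0.05, limma counted 1337 of 21372 probes, 828 higher and 509 lower in shMettl3 cells, where 1069 are expected by chance. The split turned to 69 higher and 2076 lower in the authors' values. Those ratios were not centred, so the split carries their array-wide shift (median difference -0.37 against 0.015 in the main fit). It also turned to 1465 higher and 1958 lower with no filter. Without normal replicate 1 it was 389 and 522, where the total of 911 lay below the 1057 expected. The total was also below that expected without normal replicate 2 (832 against 1065) and without shMettl3 replicate 3 (960 against 1054). With the slide row as a block 8 probes were called, all higher, and within slide row 1, which holds a single normal array, none (1777 at an unadjusted p under 0.05). Normexp background correction gave 3 calls, all lower.

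Total abundance, the summed signal of both fractions, had more calls than the ratio. Of its 45373 probes, 21771 passed the filter in Sup, so many rest mainly on IP signal. Sup alone gave 0 calls over the same probes. The channels were summed after dye normalization, so the sum may not follow the RNA amount. In shMettl3 cells 15 probes rose and 24 fell (limma, adjusted p under 0.05), none of them named. The 4 probes given next lie outside the rule for named genes. They are the largest rises and falls among called probes without a gene name whose groups do not overlap. The median size of all 39 calls was 1.58 on the log2 scale. ASMM10EP3A113461443 rose from -1.99 ± 0.16 to 0.38 ± 0.20 (log2 relative to the 75th percentile, SD, n = 3), a 5.19-fold difference with a limma adjusted p of 0.0072. The probe ASMM10EP3A100146907 rose 4.49-fold, with a limma adjusted p of 0.0424. The probe ASMM10EP3A101447718 went from 2.81 ± 0.16 to 0.06 ± 0.07 (SD, n = 3), 6.72-fold lower with a limma adjusted p of 0.00193, and ASMM10EP3A102489842 was 5.78-fold lower with a limma adjusted p of 0.0295. In IP signal alone these 4 probes differed by 2.26, 2.39, -2.79 and -1.93 on the log2 scale. The abundance differences of these probes with slide row as a block, and within slide row 1, were 2.50, 1.96, -2.72 and -2.84, and none was called in abundance. With normexp, ASMM10EP3A113461443 differed by 0.99 and ASMM10EP3A102489842 by -0.75, and both were called. The call of ASMM10EP3A113461443 was also lost without normal replicate 1 or 2 or shMettl3 replicate 2 (2.31, 2.34 and 2.26), and those of ASMM10EP3A100146907 and ASMM10EP3A102489842 without any array but shMettl3 replicate 3 (1.92 to 2.27 and -2.72 to -2.38). ASMM10EP3A101447718 kept its call under 16 of 19 alternatives. It was lost for Sup alone, with slide row as a block and within slide row 1.

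Among the named genes Apoe had the lowest unadjusted p, with an abundance 1.74-fold higher in shMettl3 cells, a log2 difference of 0.80 (95% interval 0.30 to 1.30; limma adjusted p 0.235) and all 3 arrays above the normal mean. H2-M2 differed by 0.60 (0.16 to 1.04), Anxa8 by 0.54 (0.06 to 1.02) and Cpt1a by 0.51 (0.06 to 0.96). H2-Q7, a class I histocompatibility gene whose probe may bind close relatives, differed by 0.56 (-0.03 to 1.14). The cell cycle transcription factor E2f1 differed by -0.56 (-0.99 to -0.13; limma adjusted p 0.276) and all 3 arrays below the normal mean. Bambi differed by -0.38 (-0.82 to 0.07), the caveolin gene Cav2 by -0.32 (-0.95 to 0.32), Dnajc11 by -0.23 (-0.68 to 0.21) and Nup50, a nuclear pore component, by -0.21 (-0.69 to 0.28). Rps4l differed by -0.05. None of the 36 named probes measured passed, over all probes or adjusted over the named probes alone (lowest adjusted p 0.182). The median of all probes was itself 0.17 higher in shMettl3 cells under this scaling and 0.01 higher when arrays were scaled to their median, so each difference stands against that shift. With normexp E2f1 differed by -0.09, Cav2 by -0.13, Dnajc11 by -0.14, H2-M2 by 0.32, Anxa8 by 0.33 and H2-Q7 by 0.34. With slide row as a block Apoe differed by 0.45, Cpt1a by 0.25, Cav2 by -0.00026, Nup50 by -0.36 and Dnajc11 by -0.43. Without shMettl3 replicate 3 Cav2, Nup50, Bambi and H2-Q7 differed by -0.03, -0.03, -0.25 and 0.85, without normal replicate 1 Nup50 and Dnajc11 by -0.13 and -0.13, and without normal replicate 2 Cav2 by -0.14. E2f1 is the single named member of the cell cycle list, and no statement on the list follows from 1 gene.

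**Figure D2:**
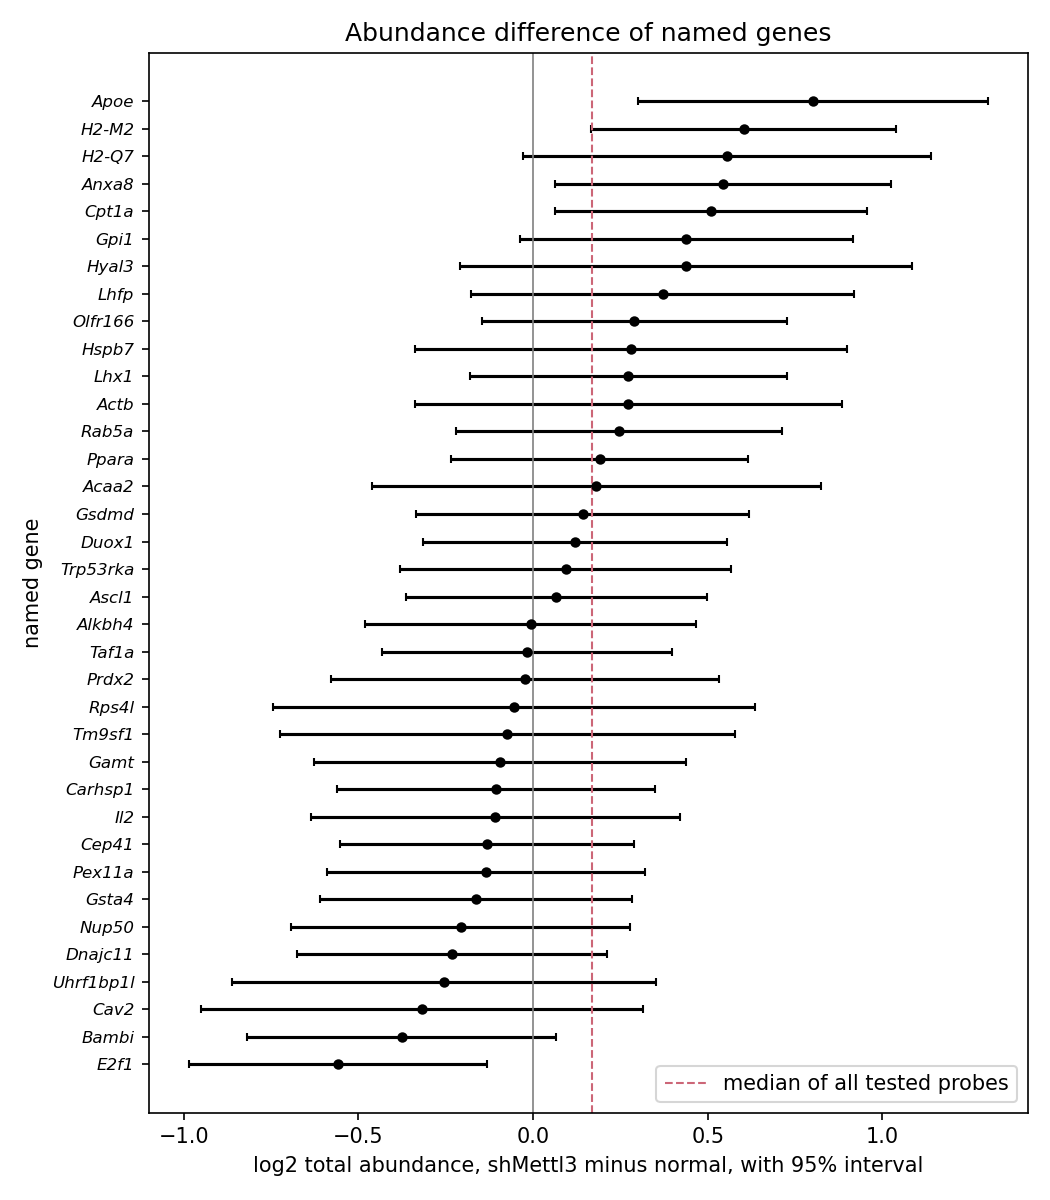
Log2 difference in total abundance, shMettl3 minus normal (x axis), with its 95% interval from limma (bars), for 36 named genes (y axis). Apoe lies at 0.80 and E2f1 at -0.56, and the dashed line marks the median of all tested probes at 0.17.

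With slide row as a block 3 probes were called, as within slide row 1, and scaling to the median turned the split of 15 higher and 24 lower into 4 and 31, quantile normalization into 24 and 68 and the authors' values into 25 and 588, while array weights gave 111 and 107. Leaving out normal replicate 1, 2 or 3 left 1, 1 or 3 calls, and leaving out shMettl3 replicate 1 or 2 left 5 or 1, against 35 without shMettl3 replicate 3, of which 22 were higher and 13 lower.

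Taken as single channels, as the authors treated them, IP and Sup differed in yield of calls in the main fit. With a replicate block the yields were alike, at 87 calls in IP and 84 in Sup. In IP signal 41 probes rose and 52 fell among 44992 (limma, adjusted p under 0.05), and 34 of these 93 probes were also among the 39 abundance calls. The abundance sum contains the IP signal, so this overlap is partly built in. H2-M2 had the lowest unadjusted p of the named genes in IP, with a log2 difference of 0.73 (95% interval 0.29 to 1.16), followed by Apoe at 0.85 (0.29 to 1.40), Anxa8 at 0.61 (0.13 to 1.09) and Cpt1a at 0.55 (0.11 to 0.99). Bambi differed by -0.42 (-0.83 to -0.01). None of these passed, with limma adjusted p of 0.189 for H2-M2 and 0.220 for Apoe. In Sup signal no probe was called among 21771, with 1815 at an unadjusted p under 0.05 in limma, 765 higher and 1050 lower. The split was 1798 and 554 with normexp, 980 and 874 scaled to the median, 3227 and 1604 with no filter and 83 and 2070 in the authors' values. That number was 1003 and 966 without normal replicates 1 and 2, where 1077 and 1085 are expected by chance. With array weights 29 Sup probes were called, 10 higher and 19 lower, and among probes detected on all 6 arrays 6 were, 1 higher and 5 lower. A replicate block called 84, 4 higher and 80 lower, though the labels do not say that the numbers pair samples. The Sup differences of E2f1 and Apoe were -0.80 (-1.43 to -0.16) and 0.70 (0.13 to 1.27), with limma adjusted p of 0.567 and 0.572; the E2f1 probe was well above background in Sup on 4 of 6 arrays. The IP count was 7 with slide row as a block and 3 within slide row 1; under the block the 93 differences kept their sign, with a median size of 1.58 against 1.53 on the log2 scale, while the median standard error of a probe was 0.28 against 0.21. The IP count was 0, 1 and 21 without normal replicates 1, 2 and 3. Without shMettl3 replicates 1 and 2 it was 37 and 1. Scaling to the median changed 41 higher and 52 lower to 23 and 104, quantile normalization to 60 and 133 and the authors' values to 8 and 281, while array weights gave 1241 and 542 and leaving out shMettl3 replicate 3 gave 42 and 32.

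Mettl3 writes m6A across many transcripts, so the design also asks for the array-wide ratio before centring. In processed signals the median log2(IP/Sup) was -0.28 ± 0.02 on normal arrays and -0.22 ± 0.08 on shMettl3 arrays (SD, n = 3; difference 0.06, exact permutation p = 0.4), and within slide row 1, with 1 normal array, they differed by 0.04. Leaving out 1 array gave differences from 0.03 without shMettl3 replicate 3 to 0.11 without shMettl3 replicate 1. The mean over probes, in place of the median, was -0.26 ± 0.01 and -0.14 ± 0.11 (SD, n = 3; difference 0.12, exact permutation p = 0.1), with all 3 shMettl3 arrays above all normal arrays. In background-subtracted signals without dye normalization the medians were 1.06 ± 0.17 and 1.25 ± 0.48 (SD, n = 3; difference 0.18, exact permutation p = 0.6). In the authors' values they were -0.49 ± 0.03 and -0.88 ± 0.39 (SD, n = 3; difference -0.38, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). There all 3 shMettl3 arrays lay below all normal arrays, at -1.31, -0.73 and -0.58, and the difference was -0.17 without shMettl3 replicate 1. The constants subtracted by the authors, IP minus Sup, were higher on shMettl3 arrays by 0.45 on average, and at 1.01 were highest for shMettl3 replicate 1. Direction thus turned with the scaling, and 3 against 3 arrays cannot reach an exact p under 0.1 in any of them.

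**Figure D3:**
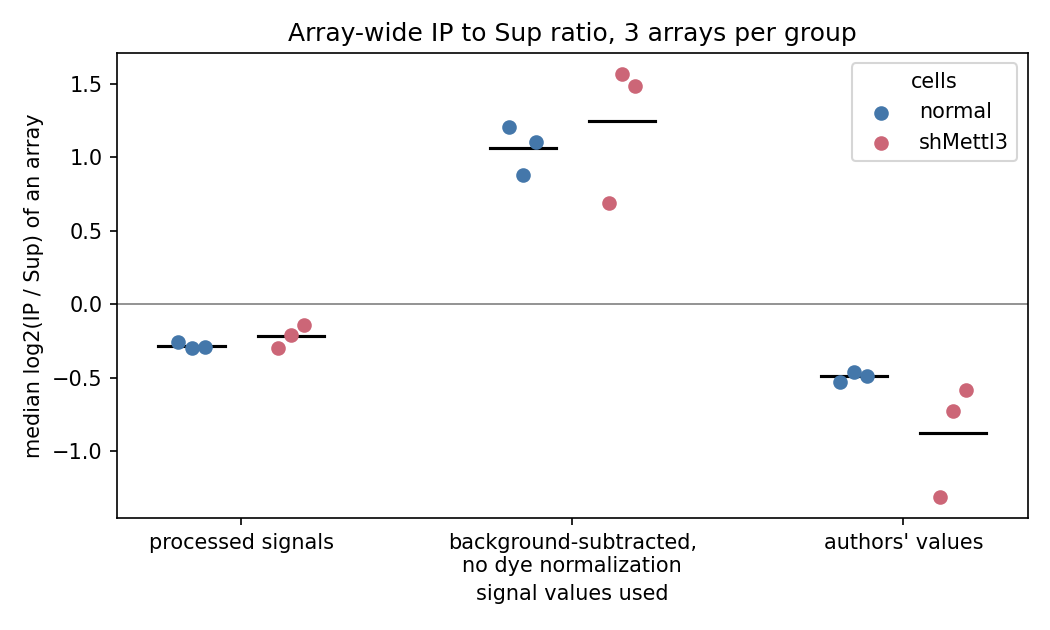
Median log2(IP/Sup) of each array (y axis) for 3 normal (blue) and 3 shMettl3 arrays (red) in 3 sets of signal values (x axis), with black lines at group means. The shMettl3 mean lies above the normal mean in processed signals (-0.22 against -0.28) and below it in the authors' values (-0.88 against -0.49).

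The series' own threshold, a change of at least 2-fold with an unadjusted p under 0.05, selected 381 probes for the m6A ratio, 323 higher and 58 lower in shMettl3 cells, of which none passed Benjamini-Hochberg adjustment in limma. No named gene reached it; the nearest was Rab5a, 1.90-fold higher. It selected 477 probes for total abundance, 282 higher and 195 lower, and 581 for IP signal, 374 higher and 207 lower, where 39 and 93 probes passed the adjustment. The split turned with the scaling. In the authors' values, whose ratios were not centred, 53 were higher and 548 lower. Scaled to the median, 103 abundances were higher and 352 lower, and 168 IP signals were higher and 399 lower. Quantile normalization gave 124 and 282 for abundance and 169 and 299 for IP signal, and the authors' values 45 and 2103 and 29 and 3989. Without normal replicate 1 the ratio count was 211, with 127 higher and 84 lower; without normal replicate 3 it was 879, and without shMettl3 replicates 1, 2 and 3 it was 721, 680 and 233. The abundance count was 948, 837 and 840 without normal replicate 3 and shMettl3 replicates 1 and 2, and the IP count 982 and 890 without normal replicate 3 and shMettl3 replicate 2. With slide row as a block the ratio count was 1600, with 1233 higher and 367 lower, the abundance count 2245 and the IP count 2077; within slide row 1 the counts were 1538, 2274 and 2102.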

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

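Slide row as a block and slide row 1 alone were chosen after the data were seen; the other alternatives were planned. Of 576 values of named genes and probes under alternatives, 567 kept their direction and 46 changed side of the threshold. These values are not independent checks, because all reuse the same 6 arrays and the slide row block and slide row 1 alone give the same estimates. They also include unnamed probes picked for large differences and levels in normal cells, whose alternatives include the level in shMettl3 cells. Kept directions therefore say little about robustness. The ratio difference of Gpi1 turned to 0.0086 with array weights and 0.21 with loess. Leaving out 1 array gave -0.30 to 0.12 for Gpi1, -0.317 to 0.026 for Gsdmd and -0.322 to 0.043 for Bambi, each above 0 without normal replicate 1. The level in normal cells turned to 0.023 for Gsta4 in probes detected on all 6 arrays, and for Tm9sf1 to -0.22 without centring and -0.049 with loess, with -0.014 (without normal replicate 3) to 0.0997 when 1 array was left out. The array-wide difference turned to -0.38 in the authors' values, which by construction are the processed signals minus their constants. The cause of other moves was not tested, except that blocks and left-out arrays leave fewer degrees of freedom.

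Against 0 calls for the m6A ratio, normexp gave 3 and the slide row block 8. Against 39 abundance calls, normexp gave 138, the authors' values 613, no filter 2, detection on all 6 arrays 90, a variance trend 115, array weights 218, quantile normalization 92, the mean of both log2 signals 19, Sup alone 0, the slide row block 3 and slide row 1 alone 3; leaving out 1 array gave 1 to 35. Against 93 IP calls, normexp gave 343, the authors' values 289, no filter 1, all 6 arrays 286, a trend 379, array weights 1783, quantile normalization 193, the slide row block 7 and row 1 alone 3; leaving out 1 array gave 0 to 74. Against 0 Sup calls, all 6 arrays gave 6, a trend 1, array weights 29, the slide row block 2 and row 1 alone 1. Quantile normalization split abundance calls into 24 higher and 68 lower, and IP calls into 60 and 133.

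At the series' own threshold, 381 ratio calls became 22 with normexp, 601 in the authors' values, 1878 with no filter, 105 on all 6 arrays, 1600 with the slide row block, 1538 in row 1 alone and 211 to 879 without 1 array. The 477 abundance calls became 75 with normexp, 2148 in the authors' values, 808 with no filter, 309 on all 6 arrays, 1980 for Sup alone, 2245 with the slide row block, 2274 in row 1 alone and 465 to 948 without 1 array; the share higher was 59.1% and fell to 30.5% with quantile normalization. The 581 IP calls became 105, 4018, 1231, 333, 2077 and 2102 with normexp, the authors' values, no filter, all 6 arrays, the slide row block and row 1 alone, and 645 to 982 without 1 array; the share higher was 64.4%, and 36.1% with quantile normalization. With no centring and with loess, 417 and 484 ratio calls were higher and 36 and 34 lower.

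With a replicate block the calls were 0 for the ratio, 105 for abundance, 87 for IP and 84 for Sup (4 higher and 80 lower), and at the series' threshold 524, 496 and 606 for ratio, abundance and IP. The labels do not say that the numbers pair samples. Deviations of same-numbered arrays correlated across probes at 0.25, 0.04 and 0.38 in abundance, 0.20, 0.09 and 0.25 in IP, 0.25, 0.08 and 0.44 in Sup and -0.09, -0.005 and 0.14 in the ratio. These values neither show nor exclude pairing, and the main fit treats the arrays as unpaired. As a hint of pairing, in abundance, IP and Sup each normal array correlated best with its own number (3 of 3). In the ratio 1 of 3 did. With the block, probes at an unadjusted p under 0.05 (limma) went from 6571 to 9498 in abundance and from 6769 to 9173 in IP. In Sup they went from 1815 to 2978 and in the ratio from 1337 to 1658. If the numbers do pair samples, the main fit leaves that pairing out. The brightest probe per gene, gene list tests and all alternatives for Mettl3 and Pten were not run for lack of gene names, and slide as a block not for lack of a further slide. Dim Sup signals limit the ratio: 16045 to 22961 probes per array were well above background in both channels.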

Other observations

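The tests of slide row on the abundance calls, of dim Sup signals, and of lower m6A as a reading of the array-wide ratio were chosen after the result was seen. Control spots for Gapdh and Pgk1, glycolytic enzymes, sit at the 3' and 5' ends of each message with 10 spots per end. The difference between ends contains the probes' own brightness, so it was compared between groups only. For Pgk1 the 3' minus 5' difference was 7.06 ± 0.20 in IP and 6.62 ± 0.18 in Sup on normal arrays (log2, SD, n = 3), and 7.20 ± 0.06 and 6.62 ± 0.25 on shMettl3 arrays (exact permutation p = 0.3 and 1). For Gapdh the differences were 0.72 ± 0.21 in IP and -0.03 ± 0.26 in Sup on normal arrays, and 0.73 ± 0.22 and 0.05 ± 0.24 on shMettl3 arrays (SD, n = 3; exact permutation p = 1 and 0.5). At the 3' end the ratio of Pgk1 relative to the array median was 0.75 ± 0.35 in normal and 1.12 ± 0.60 in shMettl3 cells (SD, n = 3; exact permutation p = 0.5), a difference of 0.37. The difference was 0.23 at the 5' end of Pgk1 and -0.04 and 0.04 at the 3' and 5' ends of Gapdh (exact permutation p = 0.6, 0.9 and 0.9).

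Spots whose IDs begin with MM9NEGATIVE, 45 per array, were well above background in IP at a rate of 35.6%, 26.7% and 51.1% on the normal arrays and 33.3%, 53.3% and 55.6% on the shMettl3 arrays. In Sup the rate was 0% to 8.89%. Spots of another negative control, 3xSLv1, stayed at or below 0.325% in both channels. What the first set was designed against is not given in the sources used here. In all, 88 probes were well above background in IP on all 3 normal and no shMettl3 arrays, and 158 the other way; in Sup the numbers were 403 and 27.

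The array-wide IP to Sup ratio was lower in shMettl3 cells in the authors' values and not in the processed signals. Background-subtracted signals, which carry neither the constants nor dye normalization, gave a difference of 0.18 with a standard error of 0.296. There 2 of 3 shMettl3 arrays lay above all normal arrays, and shMettl3 replicate 1 lay below them all, at 0.69 against 0.88 to 1.21. The step from 0.06 in the processed signals to -0.38 is fixed by the constants, which differed by 0.45. At that standard error it cannot be told apart whether the constants brought in a drop or restored one that the scanner software's dye normalization had removed. The constants tracked the mean signal of 306 spots whose IDs begin with ASSPINKEIN, with an offset that varied by 0.11 (SD over 6 arrays) in IP and 0.17 in Sup, against 0.44 to 0.55 in IP and 0.24 to 0.36 in Sup for the 6 other sets of control spots compared. What these spots measure is not given in the sources used here; were they RNA added in equal amount to each sample, the authors' difference would be scaled to it and could keep an array-wide drop that other scalings remove, which was not tested. Lower m6A with shMettl3 cannot be told apart from these, because the authors' difference of -0.38 reached an exact permutation p of 0.1 and 3 against 3 arrays allow no less. Without shMettl3 replicate 1 that difference was -0.17, which was not tested.

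The abundance calls were 39 in the labelled grouping and at most 0 in the other splits of the 6 arrays into 3 and 3, and the IP calls 93 and at most 0 (limma; at an unadjusted p under 0.05 the other splits reached at most 4410 and 3771, against 6571 and 6769); 1 of 10 splits reached each count, and 10 splits are too few to test chance. The count at the series' threshold was 477 for abundance against at most 324, and 581 for IP against at most 300, again with 1 of 10 splits. Without shMettl3 replicate 3, the array that correlated least with the others in abundance, 35 probes were called, 19 of them among the 39. They split into 22 higher and 13 lower, against 15 and 24 in the main fit. For those 19 this argues against that array alone as the source, since no call was to be left if it were. The count of 35 lies under the 39 set beforehand as the count that would exclude it, so the rest of the 39 stay open. With slide row as a block 3 probes were called, none of the 39, as the median standard error of a single probe went from 0.22 to 0.31. The 39 differences kept their sign and a median size of 1.66 against 1.58 under the block, which gives the same estimate as row 1 alone. This decides nothing, because it rests on the 1 normal array of row 1, on which the 39 were also chosen, so row stays open. The hairpin and the transfection stay open and untested.

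At the series' threshold more m6A ratios were higher than lower in shMettl3 cells, 84.8% of 381. Among probes well above background on all 6 arrays the share was 93.3%, with 98 higher and 7 lower. The imbalance was thus also present where Sup was detected on every array, although the number of calls was smaller there. With normexp 18 were higher and 4 lower. Sup signal at the same threshold was higher for 149 probes and lower for 543. The filter was chosen after the result and cannot tell lower Sup signal from a changed ratio, so dim Sup signals stay open. With no filter 884 were higher and 994 lower. Without shMettl3 replicate 3 the share was 75.1%, and with slide row as a block 77.1%, against a bound of 75% written before these shares were seen, with slide row itself added after the data were seen. The standard errors of 2.83 and 1.05 points take probes as independent, and the blocked share rests on normal replicate 1, the single normal array of its row, without which 127 of 211 (60.2%) were higher, so neither explanation can be excluded. In 3 of 10 splits the count was as large, with 480 as the highest of the others, and for calls after adjustment all 10 splits gave 0 for the ratio and for Sup signal (limma; 1337 and 1815 at an unadjusted p under 0.05, and at most 1871 and 1987 in the others); 10 splits are too few to test chance. No biological explanation was tested, since centring sets the middle of the ratios.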
